A study of Mus musculus with 12 samples.

How the data were processed

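Bulk RNA-seq of sorted mouse Tregs was read from 1 table of raw read counts per gene symbol with a column for each of the 12 libraries, as deposited. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and libraries with KAPA's RNA HyperPrep and RiboErase, which depletes ribosomal RNA. The submitters' processing notes name HISAT2 2.2.1, the genome build mm10 and Cell Ranger, with no role stated for each. The counting tool, its annotation and its strand setting are not given in the sources used here, so overlapping, antisense and near-identical genes (Tsix, histone genes, Lilr4b and Lilrb4a) are uncertain. The values are whole numbers, with total counts of 14567313 to 19121577 per library. The table holds 27 symbols turned into month-like names by a spreadsheet, which count in totals and are not named, and 2 symbols on more than 1 line, which were kept apart. Coordinates are from GENCODE vM21 on mm10, matched by symbol for 23350 of the 24421 symbols and 11947 of the 12461 tested.

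Groups follow the sample titles and the cell type field, which give 4 groups of 3 libraries; the genotype field names the alleles the other way round and was not used. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, scaled by TMM, and fitted over all 12 libraries with robust dispersions (common biological coefficient of variation 0.0768) and the quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment over the 12461 genes in each of 5 contrasts: KO against WT in each subset, eTreg against cTreg in each genotype, and the interaction. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM are TMM-normalised.

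The 27 gene lists, named in the text by what they hold, and the rule for named genes were fixed before the data were examined, as were the tests and the alternatives not said to be added later. In each contrast between 2 groups the rule takes the 10 largest rises and 10 largest falls among genes called, with all 3 libraries of 1 group above all 3 of the other and a mean log2 CPM of at least 3; for the interaction it takes 5 in each direction; and up to 4 called members of each list (2 in each direction). It leaves out predicted genes, antigen receptor segments, ribosomal or pseudogene copies, and month-like names; some genes it names were left out for length, and a gene named outside it is said to be so. Lists with at least 5 tested genes (18 of 27) were tested with camera (limma 3.58.1), two-sided, with a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a contrast; 9 lists were too small. Because 3 WT libraries are shared between the KO effect and the subset difference, 20 simulations with no KO effect give the values that sharing alone produces.

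Replicate numbers were checked for pairing by the correlation of deviations from the group means between same-numbered libraries. Only KO and WT eTreg had all 3 above 0.1 (0.343, 0.494 and 0.201), so their numbers may pair the libraries. This is a hint from the data, since the labels name no shared litter or day and libraries of unlike number were not compared. No 2 libraries of a group were duplicates: their counts differed by 3.68 to 10.3 times counting error (chi-squared per degree of freedom).

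The edgeR steps were tested on simulated data drawn from the real means and library sizes over 12461 genes, with 200 genes changed. For KO against WT in cTreg, 64 of 100 genes changed 1.5-fold and 85 of 100 changed 2-fold were recovered, with 4.49% of calls false. In eTreg, 71 and 92 were recovered, with 6.32% false. In the list test 0 of 20 unchanged lists were called in either comparison. Those lists were drawn at random from genes simulated independently, so this does not show how the test treats lists of correlated genes. In the real data the cell cycle list had an estimated correlation of 0.841 for KO against WT in cTreg.

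The alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a stricter one (CPM of at least 1 in at least 3 libraries), a minimum absolute log2 fold change of 1, the replicate block, only the 6 libraries of a contrast, and leaving out each library. For lists they were an estimated correlation and leaving out members with a mean log2 CPM below 0, and for correlations Spearman's rho and genes with a mean log2 CPM of at least 3. Added after seeing the data were library-size scaling without Rn45s, an offset fitted by splines on transcript length and GC content, the replicate block in the eTreg libraries alone, and a split of the shared WT libraries into parts of 1 and 2 for the subset axis (6 splits). No library was left out of the main results, and no other file was used here.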

Results

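Regulatory T cells (Tregs) were sorted from mice in which the gene of CD25, the alpha chain of the interleukin-2 receptor, can be deleted in Tregs with tamoxifen, and their total RNA was sequenced after ribosomal RNA depletion. Per the labels, mice received 2 mg/kg tamoxifen by the intraperitoneal route for 5 days, and cells were taken 10 days later. Central Tregs (cTreg) and effector Tregs (eTreg) were parted by a surface marker gate, and knockout (KO) Tregs were also gated as CD25-low. The 4 groups, wild-type (WT) cTreg, KO cTreg, WT eTreg and KO eTreg, had 3 libraries each, and each library came from spleen and lymph nodes pooled from 2 to 3 mice. Total counts ranged from 14567313 to 19121577 per library over 24421 gene symbols, of which 12461 were tested. The first principal component of log2 CPM (counts scaled to library size) held 72.3% of the variance and parted the subsets, and the second held 12.5% and parted the genotypes within each subset.

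**Figure D1:**
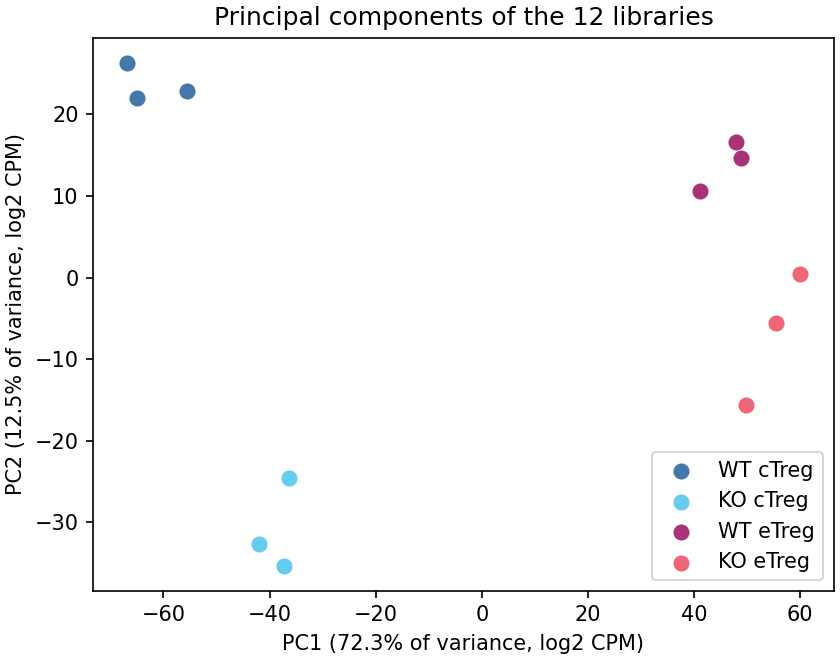
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library and 1 colour per group. The 6 cTreg libraries lie at negative and the 6 eTreg libraries at positive values of the first component, which holds 72.3% of the variance.

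Il2ra, the targeted gene (chromosome 2, 11642807 to 11693193, mm10), stood at 576, 523 and 579.8 CPM in WT cTreg replicates 1, 2 and 3 and at 122, 112 and 113 CPM in the KO cTreg replicates. It stood at 464, 562 and 542 CPM in WT eTreg and at 125, 116 and 132 CPM in KO eTreg. Its log2 fold change, KO against WT, was -2.28 ± 0.07 (SE, n = 3 per group) in cTreg and -2.07 ± 0.07 in eTreg, with adjusted p-values of 4.55e-12 and 3.20e-11 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The genotype field of the labels names the alleles the other way round from the titles, and the groups follow the titles and the cell type field. The KO cells were also gated on low CD25, so the Il2ra level is not independent of the sort.

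**Figure D2:**
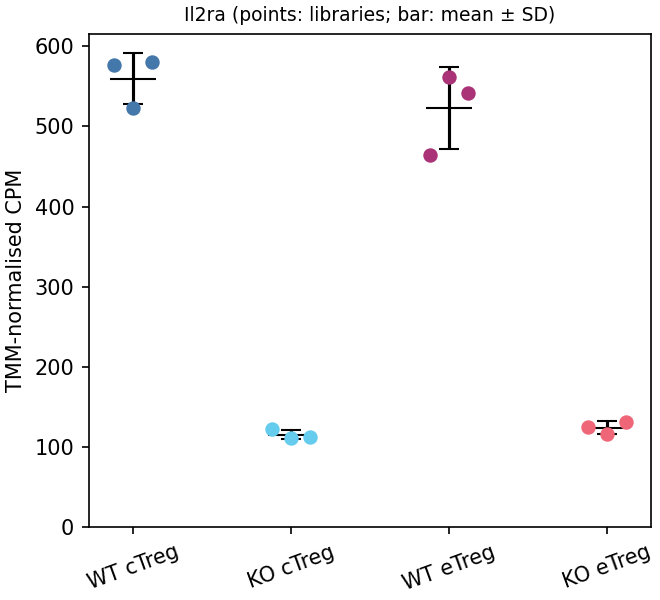
TMM-normalised CPM of Il2ra in the 4 groups, with 1 point per library and the mean ± SD of 3 libraries. Il2ra in the 6 KO libraries lies between 112 and 132 CPM, below all 6 WT libraries.

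The comparison of KO with WT cTreg asks what loss of CD25 changes in Tregs of the central gate. Genes of activated and effector Tregs rose. Gzmb, which encodes granzyme B, rose 27.9-fold (log2 fold change 4.80 ± 0.63 SE, n = 3 per group), and Il10, an inhibitory cytokine, rose 20.8-fold (4.38 ± 0.57). The inhibitory receptor gene Tigit rose from 5.24 ± 0.17 to 62.0 ± 2.69 CPM (SD, n = 3), a log2 fold change of 3.56 ± 0.07. Genes of follicular T cells rose as well, among them Il21, a helper cytokine (4.43 ± 0.55), and Il1r2, a decoy receptor of interleukin-1 (3.43 ± 0.26). Il21 was also low, at 0.178 CPM in WT and 4.01 in KO cTreg. Among the falls were Igfbp4, which marks resting T cells (from 703 to 140.0 CPM, log2 fold change -2.33 ± 0.30), the orphan receptor gene Gpr83 (-1.81 ± 0.15), and Socs2, a target of STAT5 (-1.73 ± 0.10). Of 12461 genes, 3421 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 1847 higher and 1574 lower in KO.

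Other large rises in KO cTreg were Cd22, an inhibitory lectin known from B cells (4.55 ± 0.52), the nuclease gene Dnase1l3 (4.14 ± 0.38), Sostdc1 (3.82 ± 1.01) and the chemokine gene Ccl5 (3.78 ± 0.52). In WT cTreg they stood at 0.972, 0.379, 0.155 and 0.299 CPM, in that order. The naming rule's minimum mean is taken over all 12 libraries, so a gene high in eTreg can pass it with a low WT cTreg level. The other largest falls were Fsd1l (-2.94 ± 0.18), the sorting receptor gene Sorcs2 (-2.28 ± 0.26), the cathepsin gene Ctsw (-2.08 ± 0.16), Itih5 (-2.06 ± 0.26), the receptor gene Gpr34 (-2.01 ± 0.20), Nol4l (-1.91 ± 0.18) and the dynein gene Dnah7a (-1.79 ± 0.24). In each of these genes all 3 libraries of 1 group lay above all 3 of the other, as the naming rule requires, and edgeR's adjusted p-values ran from 3.85e-15 for Tigit to 0.0208 for Sostdc1. The call of Sostdc1 ended without WT cTreg replicate 2 or 3 or KO cTreg replicate 1 or 2, with an adjusted p of up to 0.0743, and in limma-voom (adjusted p = 0.165). With gene length and GC content modelled as an offset, a choice made after seeing the data, 1602 genes were higher and 2075 lower.

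Of the 34 effector Treg genes, 31 rose in KO cTreg and 0 fell, and 32 rose adjusted over the list alone. The list's median log2 fold change was 1.48 (camera's adjusted p = 3.92e-53, and adjusted p = 0.00539 with an estimated correlation). Of the 15 follicular genes 14 rose, also 14 adjusted over the list alone, with a median of 1.31 (camera's adjusted p = 8.38e-26, and 0.0121 with an estimated correlation). Of 22 homing and adhesion genes 13 rose and 2 fell, 13 and 2 adjusted over the list alone. Cxcr3, a receptor of inflammatory chemokines, rose (3.19 ± 0.13), while Ccr7, the receptor for entry into lymph nodes (-0.61 ± 0.07), and Ccr9, a gut homing receptor (-1.13 ± 0.24), fell (camera's adjusted p = 2.97e-09 and 0.0390 with an estimated correlation).

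Of 20 genes induced by interleukin-2 and STAT5, 11 fell in KO cTreg and 6 rose, 12 and 6 adjusted over the list alone. The list's median was -0.37 and its mean -0.03, and camera's direction was down (adjusted p = 9.16e-06, and 0.0333 with an estimated correlation). Socs2 and Myc, a growth regulator (-1.51 ± 0.15), fell, while Gzmb and Prdm1, the gene of Blimp-1 (1.85 ± 0.13), rose. Of 22 Treg identity genes 11 fell and 6 rose, 12 and 7 adjusted over the list alone, with a median of -0.26 (camera's adjusted p = 3.60e-04, and 0.0390 with an estimated correlation). Gpr83 fell, and Il10 and Ebi3, a subunit of interleukin-35 (1.12 ± 0.19), rose. Of 11 interleukin-2 receptor and related genes Il2ra and Il2rb, the beta chain (-0.39 ± 0.05), fell and Jak3 and Stat5b rose, by 0.21 and 0.16; adjusted over the list alone, 3 rose and 2 fell. That list was lower by camera (adjusted p = 0.00577), but not with an estimated correlation (adjusted p = 0.158 with an estimated correlation). Its median was -0.06 and its mean -0.14, with Il2ra at -2.28. Because it includes the targeted gene, its direction is not independent of the deletion and the CD25-low gate. It was not tested without Il2ra. The calls of Jak3 and Stat5b ended without WT cTreg replicate 3 and KO cTreg replicates 1 or 2 (Jak3, adjusted p up to 0.127) or WT cTreg replicate 2 and KO cTreg replicate 3 (Stat5b, up to 0.150). They also ended with the length and GC offset (0.0968 and 0.101), that of Stat5b with only the 6 cTreg libraries (0.0797), and that of the list with no expression filter (0.268).

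Of 17 genes of resting or central T cells 8 fell in KO cTreg and 1 rose, 9 and 1 adjusted over the list alone. Igfbp4 and Bcl2, a survival gene (-1.25 ± 0.07), fell, and Tcf7, a transcription factor of resting T cells, rose by 0.42 ± 0.07 (camera's adjusted p = 1.10e-06 for the list, adjusted p = 0.0951 with an estimated correlation). Of 30 interferon response genes 18 rose and 1 fell, the same counts adjusted over the list alone, led by the antiviral genes Oas1a (1.06 ± 0.17) and Oas3 (0.85 ± 0.14), with camera's adjusted p at 2.77e-05 and adjusted p = 0.393 with an estimated correlation. Of the 8 conventional T cell cytokine genes tested, 5 rose and 1 fell, also adjusted over the list alone. Il21 and Il4 (3.50 ± 0.50) rose and Tnf fell by 0.69 (camera's adjusted p = 0.00295, adjusted p = 0.158 with an estimated correlation and 0.0933 with no expression filter). Of 30 cell cycle genes 7 rose, also 7 adjusted over the list alone, with a median of 0.90 (camera's adjusted p = 8.59e-04, adjusted p = 0.573 with an estimated correlation). Of 18 glycolysis genes 9 rose, such as Pgam1 (0.61 ± 0.10), and 2 fell, also adjusted over the list alone (camera's adjusted p = 0.0200, adjusted p = 0.573 with an estimated correlation). The glycolysis call ended without WT cTreg replicate 2 (adjusted p = 0.0943) or KO cTreg replicate 2 (0.0505).

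The lists for apoptosis, cholesterol synthesis, nuclear-encoded respiratory chain, immediate early and heat shock genes did not pass camera's test in KO cTreg, with adjusted p-values from 0.450 to 0.685. Of 18 apoptosis genes 5 rose and 2 fell, also adjusted over the list alone: the death gene Pmaip1 (1.32 ± 0.16) rose, and Bcl2 and Casp8 (-0.51 ± 0.05) fell. Of 23 cholesterol synthesis genes 2 rose and 1 fell, 2 and 0 adjusted over the list alone. Of 34 respiratory chain genes 1 fell, and 0 adjusted over the list alone. Of 23 immediate early genes 5 rose, such as Egr2 (0.59 ± 0.11), and 1, Myc, fell, also adjusted over the list alone. Of 12 heat shock genes Hspa5 rose by 0.31 ± 0.07 and 2 fell, 1 and 2 adjusted over the list alone, with Hspe1, a mitochondrial chaperonin, at -0.41 ± 0.07.

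**Figure D3:**
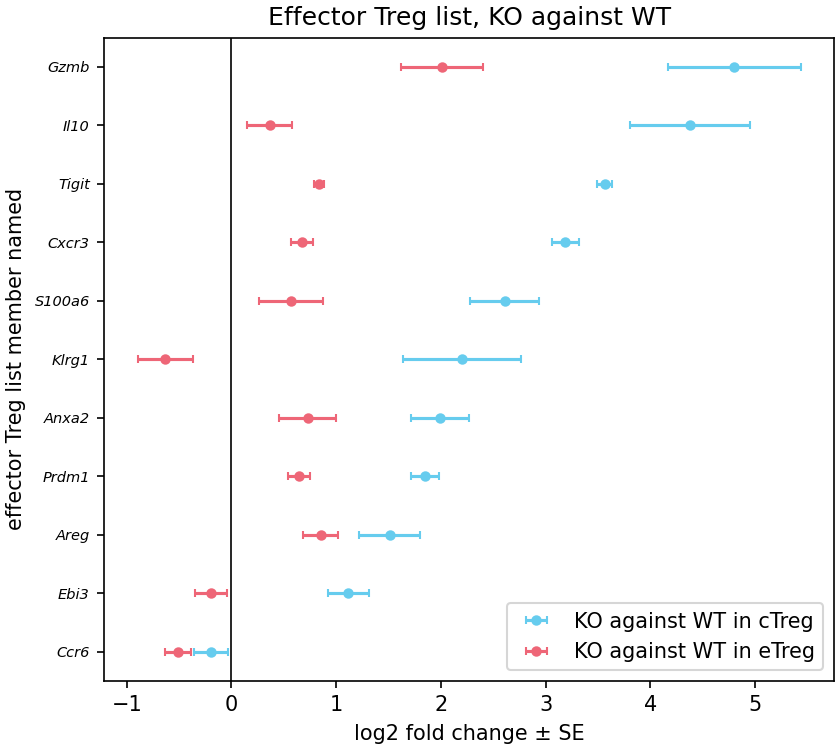
Log2 fold change ± SE, KO against WT, of the effector Treg genes named in the text, in cTreg and in eTreg (3 libraries per group), ordered by the value in cTreg. Of all 34 genes of the list 31 rose in cTreg, and in eTreg 10 rose and 1 fell.

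The comparison of KO with WT eTreg asks the same of Tregs of the effector gate. Igfbp4 (-2.74 ± 0.51 SE, n = 3 per group), Lrrc32, which encodes the TGF-beta docking protein GARP (-1.63 ± 0.11), and the cytokine gene Lta (-1.51 ± 0.09) were lower in KO eTreg. Igfbp4 was low in this gate, at 17.8 ± 10.1 CPM in WT and 2.69 ± 1.10 in KO eTreg (SD, n = 3). Its level was 703 CPM in WT and 140 in KO cTreg. Gzmb (2.01 ± 0.39) and the follicular genes Sostdc1 (1.85 ± 0.30), Il21 (1.29 ± 0.23) and Il1r2 (1.18 ± 0.14) were higher. By edgeR's quasi-likelihood test 829 genes passed an adjusted p of 0.05, 405 higher and 424 lower in KO. With library-size scaling that leaves out the ribosomal RNA gene Rn45s, chosen after seeing the data, 302 were higher and 543 lower. The eTreg replicate numbers may pair the libraries, though the labels do not say so. With replicate number as a block in the 6 eTreg libraries, a fit chosen after seeing the data, 1712 genes passed, 921 higher and 791 lower. Of the 829 genes, 813 were among them. The block was picked from deviations in these same libraries, so its count is not independent of that choice. The same 6 libraries without the block gave 771, 361 higher and 410 lower. Without WT eTreg replicate 2, WT eTreg replicate 3 or KO eTreg replicate 3 the count was 455, 497 or 462.

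The other largest rises in KO eTreg were Dnase1l3 (1.57 ± 0.20), Cd22 (1.42 ± 0.31), the serpin gene Serpina3f (1.27 ± 0.26), Rnf157 (1.23 ± 0.15), Cdk5r1 (1.23 ± 0.16) and Ccl5 (1.20 ± 0.25). The other largest falls were Sorcs2 (-2.89 ± 0.67), Dnah7a (-2.24 ± 0.18), Tbc1d16 (-1.94 ± 0.24), Fsd1l (-1.89 ± 0.15), Rell1 (-1.73 ± 0.14) and Ly6c1 (-1.55 ± 0.31), with edgeR's adjusted p-values between 9.31e-07 for Rell1 and 0.0345 for Sorcs2. Several of these calls ended when 1 library was left out. Gzmb lost its call without WT eTreg replicate 1 or 3 or KO eTreg replicate 3 (adjusted p up to 0.0746), Ccl5 without WT eTreg replicate 1 or 2 (0.0627), Serpina3f without WT eTreg replicate 1 or KO eTreg replicate 3 (0.0570) and Igfbp4 without KO eTreg replicate 1 or 3 (0.0704). Cd22 lost it without any 1 of 5 libraries, WT eTreg replicates 1 and 2 and the KO eTreg replicates (0.0865), and with the eTreg replicate block (0.217). Sorcs2 lost it without any 1 of 8 libraries, the KO cTreg and KO eTreg replicates and WT eTreg replicates 2 and 3 (0.128), with the replicate block over 12 libraries (0.0684) and in limma-voom (0.238), and Igfbp4 in limma-voom (0.0655). With only the 6 eTreg libraries Gzmb (0.0844), Sostdc1 (0.0670), Il21 (0.0623), Cd22 (0.0590), Serpina3f (0.0802) and Igfbp4 (0.0711) did not pass. Sorcs2 stood at 2.94 CPM in WT and 0.400 in KO eTreg, against 87.0 and 17.8 in cTreg. Ly6c1 stood at 2.35 and 0.800 CPM, against 60.1 and 26.8. Dnah7a, in contrast, was higher in eTreg (65.7 and 13.9 CPM) than in cTreg (14.2 and 4.05), as was Fsd1l. Whether cTreg cells inside the eTreg gate added to the levels of Igfbp4, Sorcs2 and Ly6c1 was not tested.

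Of the 20 genes induced by interleukin-2 and STAT5, 8 fell in KO eTreg and 4 rose, 11 and 4 adjusted over the list alone, and of 22 Treg identity genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone. For both lists camera's adjusted p was 5.19e-11, and 0.00511 with an estimated correlation. Socs2 (-1.35 ± 0.09) and Foxp3, the transcription factor that defines Tregs (-0.48 ± 0.06), fell; Foxp3 also fell in KO cTreg (-0.79 ± 0.06) and is named here after its values were seen. Of 15 follicular genes 7 rose and 0 fell, 14 adjusted over the list alone (camera's adjusted p = 2.56e-14, and 0.0424 with an estimated correlation). Of 34 effector genes 10 rose, such as Areg, a growth factor of tissue repair (0.85 ± 0.17), and 1, Ccr6, fell (-0.51 ± 0.12), the same adjusted over the list alone, with camera's adjusted p at 7.99e-08 and adjusted p = 0.156 with an estimated correlation. Ccr6 lost its call without WT eTreg replicate 1 or 2 or any KO eTreg replicate (adjusted p up to 0.0872). Of 17 resting genes 8 fell and 1 rose, 9 and 2 adjusted over the list alone (camera's adjusted p = 3.55e-07, adjusted p = 0.112 with an estimated correlation). Of 30 interferon genes 8 rose, 17 adjusted over the list alone (camera's adjusted p = 2.21e-10, adjusted p = 0.184 with an estimated correlation).

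The interleukin-2 receptor list was lower in KO eTreg by camera (adjusted p = 0.00126) while its median was 0.05 and its mean -0.12: 2 of 11 fell and 0 rose, 2 and 1 adjusted over the list alone (adjusted p = 0.112 with an estimated correlation). It includes the targeted gene Il2ra (-2.07), so its direction is not independent of the deletion and the CD25-low gate. It was not tested without Il2ra. Of 8 cytokine genes 2 rose and 1, Tnf (-0.70 ± 0.12), fell, 3 and 1 adjusted over the list alone (camera's adjusted p = 0.0327, adjusted p = 0.372 with an estimated correlation). The glycolysis list was higher (1 of 18 rose, 2 adjusted over the list alone; camera's adjusted p = 0.0327, adjusted p = 0.712 with an estimated correlation). The cholesterol synthesis and respiratory chain lists were lower, with 0 members called in either, also adjusted over the list alone (camera's adjusted p = 0.0243 and 0.0478, and adjusted p = 0.783 with an estimated correlation for both). The respiratory chain call ended with the replicate block (adjusted p = 0.0641) and the length and GC offset (0.145). With no expression filter the interleukin-2 receptor (0.456) and cytokine (0.0839) calls ended, the latter also with the offset (0.0533) and without members of low expression (0.373). The cytokine, glycolysis, cholesterol synthesis and respiratory chain calls ended on leaving out 1 library. The cytokine call ended without WT cTreg replicate 2, WT eTreg replicate 3 or KO eTreg replicate 2 (adjusted p up to 0.423), and glycolysis without WT eTreg replicate 1 or 3 or KO eTreg replicate 2 (0.621). The cholesterol synthesis call ended without WT eTreg replicate 2 or KO eTreg replicate 1 (0.787), and the respiratory chain without WT cTreg replicate 2 or 3, any KO cTreg replicate, WT eTreg replicate 2 or 3 or KO eTreg replicate 1 or 3 (up to 0.342).

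Other lists did not pass camera's test in KO eTreg. Of 18 apoptosis genes 4 rose and 2 fell, 4 and 3 adjusted over the list alone, with Bcl2 at -0.73 ± 0.07 (camera's adjusted p = 0.523). Of 22 homing genes 2 rose, among them Cxcr3 (0.67 ± 0.11), and 3 fell, 3 and 3 adjusted over the list alone (0.989). Of 23 immediate early genes 1 rose and 1 fell, also adjusted over the list alone (0.857), and Myc fell (-1.07 ± 0.15). Of 30 cell cycle and 12 heat shock genes 0 were called, also adjusted over the list alone (0.395 and 0.989). The cell cycle list passed without WT eTreg replicate 2 (adjusted p = 0.00384) or KO eTreg replicate 1 (0.00268).

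The difference between the KO effects, eTreg minus cTreg, asks whether CD25 loss acted alike in the subsets on the log2 scale. The KO effect on Il10 was lower by 4.02 in eTreg (log2 difference -4.02 ± 0.64 SE), since Il10 stood at 0.129 CPM in WT cTreg, 2.81 in KO cTreg, 12.4 in WT eTreg and 16.0 in KO eTreg. The differences for Il21 (-3.15 ± 0.66), Cd22 (-3.13 ± 0.66), Cxcr6, a tissue homing receptor (-2.94 ± 0.47), and Tigit (-2.73) were also negative. The most positive were Ctsw (1.36 ± 0.22), Gpr34 (1.21 ± 0.27), Osgin1 (1.20 ± 0.23), Apol9b (1.11 ± 0.17) and Nol4l (1.11 ± 0.23), which fell less in eTreg. In edgeR's interaction test 474 genes passed, 100 positive and 374 negative, and with the length and GC offset 233 were positive and 357 negative. Il21 lost its call without any WT cTreg replicate or KO cTreg replicate 2 (adjusted p up to 0.0849), Gpr34 without WT cTreg replicate 1, KO cTreg replicate 2 or 3 or KO eTreg replicate 3 (0.0678), and Cd22 without WT cTreg replicate 1 or 3, KO cTreg replicate 1 or 2, WT eTreg replicate 1 or 3 or KO eTreg replicate 1 or 3 (up to 0.118) and with the replicate block over 12 libraries (0.0755). In limma-voom Il10 (adjusted p = 0.0548), Il21 (0.240), Cd22 (0.186), Cxcr6 (0.0980) and Gpr34 (0.0658) did not pass. Without KO cTreg replicate 2, 314 genes passed.

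Of the 34 effector genes 24 had a negative difference and 0 a positive one, 30 and 0 adjusted over the list alone (median -1.29, camera's adjusted p = 1.35e-68, and 0.00169 with an estimated correlation). Of 15 follicular genes 8 were negative, 9 adjusted over the list alone (6.27e-20, and 0.0180 with an estimated correlation), and of 22 homing genes 9, 11 adjusted over the list alone (6.62e-17, and 0.0120 with an estimated correlation). The cytokine list was lower with 4 of 8 genes negative, also adjusted over the list alone (camera's adjusted p = 1.94e-04, adjusted p = 0.117 with an estimated correlation). The cell cycle and respiratory chain lists were lower with 0 genes called in either, also adjusted over the list alone (camera's adjusted p = 0.00151 and 0.0338, adjusted p = 0.830 with an estimated correlation for both). The cell cycle call ended without KO cTreg replicate 2, WT eTreg replicate 2 or KO eTreg replicate 1 (adjusted p up to 0.0913), and the respiratory chain call without WT cTreg replicate 2, KO cTreg replicate 2 or 3, WT eTreg replicate 2 or KO eTreg replicate 1 or 3 (up to 0.264), with the replicate block over 12 libraries (0.0685) and with the length and GC offset (0.325). Resting, glycolysis and cholesterol synthesis genes did not pass (camera's adjusted p = 0.168, 0.381 and 0.381). Resting genes passed without WT eTreg replicate 2 (0.00957) or KO eTreg replicate 1 (0.0223). So did glycolysis genes without KO eTreg replicate 2 (0.0365), and cholesterol synthesis genes without WT cTreg replicate 3 (0.0201) or WT eTreg replicate 1 (0.00368). The interleukin-2/STAT5 list had a median difference of 0.19 and a mean of -0.22 and did not pass (0.706); 2 genes were positive, such as Bcl2 (0.52 ± 0.10), and 3 negative, such as Nfil3 (-1.37 ± 0.16), 7 and 5 adjusted over the list alone.

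Across the 12461 tested genes, which are not independent replicates, the KO effects in cTreg and eTreg had Pearson's r = 0.559 (jackknife SE 0.0781 over libraries) and Spearman's rho = 0.521. Their covariance was 0.121, and unchanged groups simulated 20 times gave -4.35e-04 on average. Without KO eTreg replicate 2, r was 0.451. Of the genes called, 321 were higher in both subsets (60.0 for independent lists), 338 lower in both (53.6) and 9 called in opposite directions. Of the 3421 genes called in cTreg, 87.2% had the same sign in eTreg and 95.3% a smaller fold change there, a share that selection on the cTreg value raises. Of the 829 called in eTreg, where selection acts the other way, 94.7% had the same sign in cTreg and 33.5% a smaller fold change there.

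**Figure D4:**
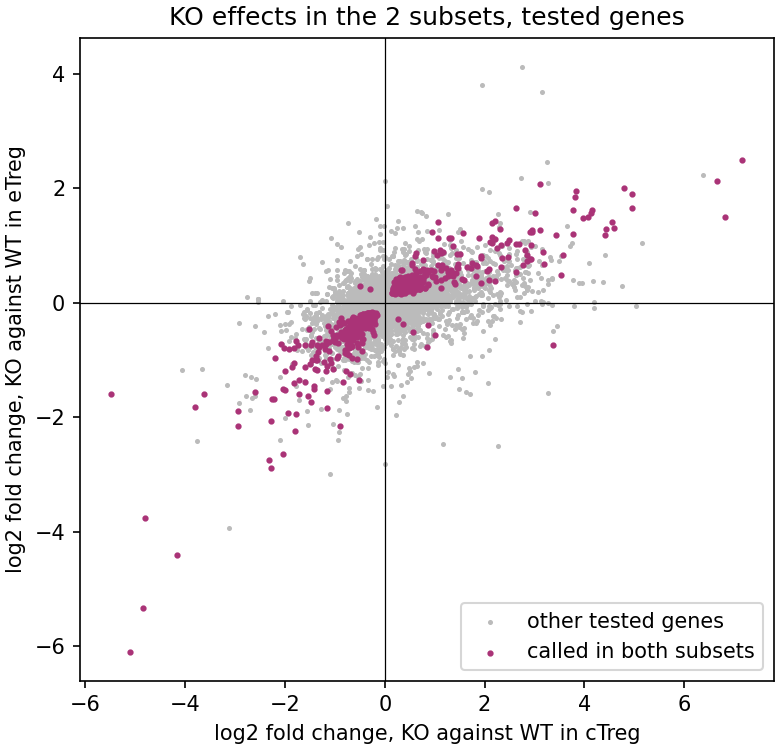
Log2 fold change, KO against WT, in cTreg (x axis) and eTreg (y axis), with 1 point per tested gene. Genes called in both subsets are coloured; 321 of them are higher and 338 lower in both, and Pearson's r over all points is 0.559.

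The comparison of eTreg with cTreg in WT describes the subset difference without the deletion. Il10 rose by 6.53 ± 0.45 (log2, SE, n = 3 per group), Sostdc1 by 6.36 ± 0.71, Il21 by 5.62 ± 0.48, Klrg1, a receptor of differentiated effector cells, by 5.41 ± 0.43 and Cxcr6 by 5.12 ± 0.34. Lower in eTreg were Igfbp4 (-5.27 ± 0.35), Sorcs2 (-4.83 ± 0.32), the surface antigen gene Ly6c1 (-4.66 ± 0.18) and the adenylyl cyclase gene Adcy6 (-3.86 ± 0.24). Further rises were Asb2 (6.03 ± 0.26), Mid2 (5.11 ± 0.44) and the amino acid transporter gene Slc7a10 (4.92 ± 0.38), and further falls Prr7 (-3.44 ± 0.15), the kinase gene Dapk1 (-3.32 ± 0.19) and the histone genes Hist1h2af, Hist1h2ah, Hist1h2ag and Hist1h3c (-3.68 to -3.23). The myeloid receptor genes Lilr4b (6.08 ± 0.54) and Lilrb4a (4.82 ± 0.42) rose, but they are near-identical copies whose reads may be split, as histone genes are. By edgeR's quasi-likelihood test 8914 genes passed, 4449 higher and 4465 lower, 2593 of them by at least 2-fold. The even split depended on choices made after seeing the data. With the length and GC offset 3237 were higher and 4174 lower, and with library-size scaling without Rn45s 4930 were higher and 4011 lower. Across 11947 genes the fold change had Spearman's rho of -0.554 with GC content and 0.205 with transcript length.

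In WT, 31 of 34 effector genes rose in eTreg and 0 fell, also adjusted over the list alone (camera's adjusted p = 2.00e-21, and 0.0379 with an estimated correlation). Of 17 resting genes 16 fell, also adjusted over the list alone, with Ccr7 at -2.07 ± 0.07 and Il7r the only one that rose (1.69 ± 0.31) (camera's adjusted p = 1.91e-15, and 0.0314 with an estimated correlation). The other 8 calls did not hold with an estimated correlation. All 15 follicular genes rose (camera's adjusted p = 1.15e-10, adjusted p = 0.0804 with an estimated correlation), as did 13 of 22 Treg identity genes, with 4 lower (6.47e-04, adjusted p = 0.0784 with an estimated correlation). So did 15 of 22 homing genes, with 5 lower (0.0244, adjusted p = 0.505 with an estimated correlation), and 7 of 8 cytokine genes (0.0184, adjusted p = 0.352 with an estimated correlation). Lower were 22 of 34 respiratory chain genes, with 6 higher (0.0167, adjusted p = 0.733 with an estimated correlation), 11 of 18 glycolysis genes, with 1 higher (0.0244, adjusted p = 0.725 with an estimated correlation). Also lower were 19 of 30 interferon genes, with 5 higher (0.0244, adjusted p = 0.747 with an estimated correlation), and 6 of 11 interleukin-2 receptor genes, with 2 higher (0.0244, adjusted p = 0.352 with an estimated correlation). Counts adjusted over the list alone were the same for these lists. The interferon call ended without WT cTreg replicate 1 (adjusted p = 0.0558) and the homing call without KO eTreg replicate 1 (0.0527). With the length and GC offset the glycolysis (0.463) and interleukin-2 receptor (0.182) calls ended. Cholesterol synthesis genes (10 of 23 lower, 1 higher, also adjusted over the list alone; camera's adjusted p = 0.151) passed with no expression filter (0.0378) or without WT eTreg replicate 2 (0.0201). The STAT5 list had a mean of 0.08 against a median of -0.44 and camera's direction down (adjusted p = 0.223), and the apoptosis list a mean of 0.06 against a median of -0.01 (0.942).

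In KO, eTreg against cTreg, Lilr4b (5.00 ± 0.41), its near-identical copy Lilrb4a (4.82), Sostdc1 (4.39 ± 0.39), Mid2 (3.47 ± 0.32), the adhesion gene Dscam (3.40 ± 0.36) and the receptor gene Nr3c2 (3.33) rose most. Penk, the precursor of enkephalin (3.28 ± 0.10), Asb2, the titin gene Ttn and Gprasp2 (2.93 to 3.18) followed. Igfbp4 (-5.68 ± 0.44), Sorcs2 (-5.44 ± 0.50), Ly6c1 (-5.04 ± 0.22) and Adcy6 (-4.36 ± 0.26) fell most. By edgeR's quasi-likelihood test 8968 genes passed, 4503 higher and 4465 lower. With the length and GC offset, chosen after seeing the data, 7173 passed, 3515 higher and 3658 lower, and 5946 of them were among the 8968. Across 11947 genes the fold change without the offset had Spearman's rho of -0.599 with GC content and 0.220 with transcript length. Of the effector genes 26 rose and 3 fell, also adjusted over the list alone, with Klrg1 at 2.58 ± 0.33 and the calcium-binding protein gene S100a6 at -1.29 ± 0.29 (camera's adjusted p = 4.49e-06, adjusted p = 0.358 with an estimated correlation). Of the other 6 lists called, resting (1 of 17 rose, 16 fell) and Treg identity genes (16 rose, 4 fell) each had adjusted p = 0.0866 with an estimated correlation. Follicular (15 of 15 rose), glycolysis (13 of 18 fell, 14 adjusted over the list alone), respiratory chain (26 of 34 fell) and interferon genes (17 of 30 fell) had 0.358 to 0.705. With the length and GC offset the glycolysis call ended (0.222). Lists that missed the threshold narrowly were cell cycle (20 of 30 fell, 1 rose, median -0.93), cholesterol synthesis (12 of 23 fell, 1 rose, median -0.53), interleukin-2 receptor (6 of 11 fell, 2 rose) and cytokine genes (7 of 8 rose, 0 fell), with the same counts adjusted over the list alone. The first 3 had camera's adjusted p = 0.0513 and cytokines 0.0516; with an estimated correlation they had 0.860, 0.860, 0.514 and 0.600. All 4 passed with the replicate block over 12 libraries (0.0194 to 0.0289). With the offset cell cycle (0.00106), cholesterol synthesis (0.00497) and cytokine genes (0.0159) passed, and with no expression filter the same 3 did (0.00177, 0.00404 and 0.0221). Cell cycle and cholesterol synthesis also passed with DESeq2 size factors (0.0385 each) and without Rn45s in the scaling (0.0364 each). On leaving out members of low expression, cell cycle, cholesterol synthesis and interleukin-2 receptor genes passed (0.0484 each). All 4 passed without KO cTreg replicate 3, WT eTreg replicate 1 or WT eTreg replicate 3 (0.0195 to 0.0496). Cell cycle genes also passed without KO cTreg replicate 1, WT eTreg replicate 2 or KO eTreg replicate 2 (0.00991 to 0.0350), and interleukin-2 receptor genes without KO cTreg replicate 1 or 2 (0.0280 and 0.0277). Cholesterol synthesis also passed without WT cTreg replicate 2 or 3, KO cTreg replicate 1, WT eTreg replicate 2 or KO eTreg replicate 2 or 3 (0.0202 to 0.0474), and cytokine genes without KO eTreg replicate 1 or 3 (0.0278 and 0.0422). The homing list had a median of 0.37 and camera's direction down (adjusted p = 0.980).

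The KO effect was also set against the subset difference in WT, across 12461 genes. In cTreg r was 0.533 and rho 0.338, with a covariance of 0.380 against 0.0493 in simulations without a KO effect that share the WT libraries, a difference of 0.330. In eTreg r was 0.220, with a covariance of 0.0831 against -0.0228, a difference of 0.106; without WT eTreg replicate 2, r was 0.115. Of genes higher in KO cTreg, 1207 were also higher in WT eTreg than in WT cTreg (659 for independent lists) and 317 lower (662). Both contrasts subtract the same WT cTreg libraries, which favours a shared direction, so the lists are not independent and those baselines are rough. With the shared WT libraries split, 1 part set against KO and the other used in the subset difference, a choice made after seeing the data, the covariance over 6 splits was 0.392 in cTreg (0.336 to 0.451) and 0.103 in eTreg (0.0699 to 0.158).

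Transcripts of other cell types were mostly low. The highest by group mean were Pecam1 (119 to 269 CPM), Cd74 (15.3 to 53.8), Cst3 (16.6 to 23.3), Cd79b (8.15 to 14.5), Eomes (1.90 to 13.8) and Cd8b1 (5.32 to 10.9). Of B cell markers Cd74, which activated T cells also express, rose in KO cTreg from 15.3 to 32.1 CPM and Cd79b fell (1 of 5 up and 1 down; 0 up and 1 down in eTreg). Of 3 natural killer cell markers tested, Gzma (3.84 ± 0.79) and Eomes (1.87 ± 0.40) rose in KO cTreg beside the effector genes, and Gzma in KO eTreg (1.96 ± 0.47, lost without WT eTreg replicate 1 or 3 or KO eTreg replicate 2 or 3, adjusted p up to 0.0773). Klrb1c was called in neither (adjusted p = 0.299 and 0.161), but KO eTreg replicate 2 stood apart, at 11.4 CPM (217 counts) against at most 1.85 CPM in any other library. Gzma (0.0645) and Zbtb46 (0.0594) did not pass with only the 6 eTreg libraries, nor Zbtb46 in DESeq2 (0.0789). Of 3 myeloid markers Itgam rose in KO cTreg (1.66 ± 0.51, at most 6.13 CPM in any library; lost without WT cTreg replicate 1 or 2 or KO cTreg replicate 2 or 3, adjusted p up to 0.108). Of 2 dendritic cell markers Zbtb46 rose in KO eTreg (0.88 ± 0.24). Of 3 stromal markers Col1a1 rose (2.04 ± 0.40) and Pecam1, which T cells also express, fell (-0.42 ± 0.06) in KO cTreg, and Col1a2 fell in KO eTreg (-2.41 ± 0.31). Of 1 CD8 (Cd8b1), 4 erythroid and 1 platelet marker tested 0 were called in either KO comparison. Of 2 sex-linked genes tested, Xist and Tsix, 0 were called in either KO comparison. Of 6 pan T cell genes Cd4 rose in KO cTreg (0.47 ± 0.06) and 0 were called in KO eTreg. Zbtb46 lost its call without WT eTreg replicate 2 or 3 or KO eTreg replicate 1 or 3 (adjusted p up to 0.166), and Cd79b in cTreg without WT cTreg replicate 1 or KO cTreg replicate 1 or 3 (0.0586). The X-linked Xist was present at 1287 CPM in WT cTreg, 1467 in KO cTreg, 3420.0 in WT eTreg and 3837 in KO eTreg. Y-linked genes had at most 1 count, and 0 of the 13 mitochondrially encoded genes are in the table.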

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

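The tests of Rn45s scaling and of effector Tregs inside the KO cTreg gate were chosen after the result was seen, as were the thresholds of the latter; the predictions for length and GC and for the splits were written before their results, the former with an offset added after seeing the data.

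The KO effect differed between the subsets by edgeR's interaction test in 474 genes and, by camera, in 6 lists, all with a smaller log2 value in eTreg. The order can turn in CPM. Tigit rose from 5.24 to 62.0 CPM in cTreg and from 106 to 190 CPM in eTreg. Il21 rose from 0.178 to 4.01 and from 9.06 to 22.2 CPM. Klrg1 rose from 1.01 to 4.59 CPM in cTreg but was lower in KO than in WT eTreg (27.4 against 42.5). A smaller log2 value therefore does not mean a smaller change in CPM. The median differences (log2, eTreg minus cTreg) were -1.29 for effector, -0.83 for follicular, -0.51 for homing, -1.06 for cytokine, -0.68 for cell cycle and -0.14 for respiratory chain genes. With an estimated correlation 3 of the 6 passed; cytokine (adjusted p = 0.117), cell cycle (0.830) and respiratory chain genes (0.830) did not. Among effector and helper genes the KO effect was lower in eTreg for Il10 (-4.02), Il21 (-3.15), Il4 (-2.77), Klrg1 (-2.83), Tigit (-2.73), S100a6 (-2.04), Ebi3 (-1.31), Prdm1 (-1.20), Nfil3 (-1.37) and Il1r2 (-2.25). Chemokine and surface genes were lower too: Cxcr6 (-2.94), Cxcr3 (-2.52), Ccl5 (-2.58) and Cd22 (-3.13). So were Asb2 (-2.86), Dnase1l3 (-2.56), Slc7a10 (-2.27), Penk (-1.07), Pmaip1 (-0.76) and Pgam1 (-0.58). It was higher for Ctsw (1.36), Gpr34 (1.21), Osgin1 (1.20), Apol9b (1.11), Nol4l (1.11), Fsd1l (1.05), Gpr83 (1.01), Bcl2 (0.52), Pecam1 (0.40) and Casp8 (0.37). Asb2, Klrg1, Slc7a10, S100a6, Tigit, Penk and others outside the naming rule for this comparison were taken after their values were seen. Of these 30 genes 19 kept their call without any 1 library. Beside Cd22, Il21 and Gpr34, calls ended on leaving out 1 library for Gpr83 (adjusted p = 0.0606 without KO cTreg replicate 2; also KO cTreg replicate 3, WT eTreg replicate 2 or KO eTreg replicate 3), Pgam1 (0.0916 without KO cTreg replicate 2; also any WT cTreg replicate, KO cTreg replicate 3, WT eTreg replicate 2 or KO eTreg replicate 3) and Pmaip1 (0.0912 in limma-voom and 0.141 without KO cTreg replicate 3; also any library but WT cTreg replicate 3 and KO cTreg replicate 1). They also ended without any WT cTreg replicate for Ccl5 (0.145 without WT cTreg replicate 3; also KO cTreg replicate 1 or 3 or KO eTreg replicate 1 or 3) and Slc7a10 (0.126 without WT cTreg replicate 3; also KO cTreg replicate 1 or 2 or KO eTreg replicate 3). The same held for Klrg1 (0.106 without KO cTreg replicate 3; also the other KO cTreg replicates, WT eTreg replicate 2 or 3 or KO eTreg replicate 3) and S100a6 (0.118 without WT cTreg replicate 3; also KO cTreg replicate 2 or 3, any WT eTreg replicate or KO eTreg replicate 3). Fsd1l lost its call without WT cTreg replicate 3, any KO cTreg replicate, WT eTreg replicate 1 or KO eTreg replicate 3 (up to 0.0722).

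The effector list rose in KO cTreg with a median log2 fold change of 1.48. That median was 1.42 with the length and GC offset, which argues against length or GC content as the cause. It was 1.47 without Rn45s in the scaling. That scaling moved the median over all tested genes only from 0.00140 to 9.12e-04, so it does not decide on ribosomal RNA as the cause. If KO eTreg cells inside the cTreg gate were the cause, each of the 31 risen genes would need about the same share of them; the shares had quartiles of 30.4% and 63.2%, a ratio of 2.08 ± 0.20 (jackknife SE; 2.00 to 2.33 leaving out 1 library, 2.08 from fitted folds, 3.05 with the offset). Against a threshold of 2 set after rough shares had been seen, that ratio does not decide. A share of KO eTreg RNA also brings that share of every eTreg transcript. Outside the list, 74 genes were at least 8-fold higher in WT eTreg than in WT cTreg and at 10 CPM or more in KO eTreg. Of these, 33 stood in KO cTreg below 28.8% of their KO eTreg level (the first quartile less 2 of its jackknife SE) by more than 2 SE of their fold. With the limit recomputed in each setting the count was 20 with the offset, 33 without Rn45s in the scaling and 26 to 34 leaving out 1 library. Over the 74 genes the KO cTreg level had a median of 23.3% of the KO eTreg level, with quartiles of 15.1% and 29.6%. The median share that the list's risen genes would need was 37.5%. Sostdc1 stood at 4.80%, Penk at 10.3% and Asb2 at 11.1%, all below the first quartile of the 74. These values argue against cells with the profile of the KO eTreg libraries as the cause for the list as a whole; a smaller share of them may account for part. A mixture cannot exceed both its parts, and 2 genes, S100a6 and Anxa2 (the latter taken after its values were seen), were lower in KO eTreg than in KO cTreg (-1.29 ± 0.29 and -1.27 ± 0.26; -0.90 ± 0.25 and -1.07 ± 0.25 with the offset), so KO eTreg cells alone do not account for these 2. Effector cells of another profile inside the cTreg gate, the CD25-low gate and an effect of the deletion stay open.

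In each contrast of 2 groups the libraries form 10 splits, too few for a share under 0.05, and only 1 split, the real one, gave as many genes. The real counts and the highest among the other splits were 3421 and 0 for KO against WT in cTreg, 829 and 0 in eTreg, 8914 and 0 for the subsets in WT, and 8968 and 2 in KO. For eTreg, where the numbers may pair the libraries, the other splits that part all 3 pairs also gave at most 0. For the interaction, 5 of 100 splits drawn from 200 gave at least 474 genes, so chance was not excluded at 0.05. The other 4 all kept the true cTreg genotypes, and the highest, 1743, several times the real count, points to the structure of the samples, because regrouped eTreg libraries leave the KO effect in cTreg in the difference. Of 82 splits that regrouped both subsets 0 reached it, and the highest gave 0. A regrouped split mixes the real groups, so a real difference adds to the within-group spread and can lower the count. The low counts of such splits, here and in the contrasts of 2 groups, therefore do not show how many genes chance alone would call.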

How the results depend on the processing

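The length and GC offset, scaling without Rn45s, the eTreg replicate block and the split of the WT libraries were chosen after seeing the data. Over 360 gene results, 6505 of 6840 alternative values kept their direction and their side of the threshold, 290 lost the call, 33 gained one and 12 reversed; over 90 list results, 1579 of 1705 did, 75 lost, 51 gained and 0 reversed. All 12 reversals came with the offset between the subsets: Iigp1 -0.10, Gbp7 -0.0752, Cst3 0.30, Cd3g -0.21 and Lck 0.0371 in WT, and Jak3 0.00908, Capg 0.26, Bax 0.12, Sc5d -0.21, Gbp7 -0.11, Cst3 0.29 and Cd3g -0.28 in KO. With an absolute log2 fold change of at least 1, counts were 742 (KO cTreg), 136 (KO eTreg), 2593 and 2482 (subsets in WT and KO) and 215 (interaction). Leaving out 1 library gave 455 to 890 genes in KO eTreg (455 without WT eTreg replicate 2, 497 without WT eTreg replicate 3, 462 without KO eTreg replicate 3) and 314 to 570 for the interaction (314 without KO cTreg replicate 2). The replicate block gave 1712 in the 6 eTreg libraries alone, against 771 in the same libraries without it, and over 12 libraries 3410, 857, 8951, 8986 and 558 in the 5 contrasts; the block's effect on named genes and lists stands beside them, and of the lists it added 4 calls in KO between the subsets (11 against 7): cell cycle, cholesterol synthesis, interleukin-2 receptor and cytokine genes. That count was also 11 without KO cTreg replicate 3, WT eTreg replicate 1 or WT eTreg replicate 3 (7 to 11 over libraries). With an estimated correlation 5, 3, 2, 0 and 3 lists passed. The correlation of KO effects was 0.451 to 0.550 leaving out 1 library (0.451 without KO eTreg replicate 2) and 0.672 at a mean log2 CPM of at least 3. With the WT libraries split, r along the subset axis was 0.457 in cTreg and 0.235 in eTreg on average. Along that axis rho was 0.338 in cTreg, and r in eTreg was 0.115 to 0.242 leaving out 1 library (0.115 without WT eTreg replicate 2) and 0.358 at a mean log2 CPM of at least 3. The cause was not tested, except that a minimum fold removes genes by construction and a left-out library leaves fewer. Depth limits genes near 1 CPM or less, such as Il10 in WT cTreg.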

Other observations

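The tests of Rn45s scaling and of Nnt were chosen after the result was seen; the predictions for length and GC and for genes near Il2ra were written before their results, the former with an offset added after seeing the data.

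Histone genes and ribosomal RNA, named here after their values were seen, differed between groups. Of 65 replication-dependent histone genes tested, 30 rose in KO cTreg and 0 fell (median log2 fold change 1.01), and 0 were called in KO eTreg. In eTreg against cTreg 54 fell and 2 rose in WT (median -1.57), and 60 fell in KO (median -2.44). Histone genes held 0.156 ± 0.0279% of counts in WT cTreg, 0.304 ± 0.0906% in KO cTreg, 0.0766 ± 0.0151% in WT eTreg and 0.0896 ± 0.0232% in KO eTreg (SD, n = 3). Rn45s, the ribosomal RNA precursor, held 23.7 ± 1.13% in WT cTreg, 18.2 ± 0.190% in KO cTreg, 4.24 ± 0.120% in WT eTreg and 3.25 ± 0.0629% in KO eTreg.

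Most tested genes, 8914 in WT, differed between eTreg and cTreg. With Rn45s left out and plain library-size scaling 8941 passed. The median log2 fold change over tested genes was 2.71e-04 with TMM and 0.0731 with that scaling. Both scalings were thus close, the count had little room to fall, and the comparison does not decide on ribosomal RNA as the cause. With the length and GC offset 7411 passed, so a length or GC trend may account for part of the calls but not for most, and the offset moved fold changes by a median of 0.321 in size. Degradation or other handling that differed between the subsets was not tested and stays open beside the subset difference itself.

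KO and WT mice may differ in strain background near or away from Il2ra. Among the 643 genes with known coordinates, other than Il2ra, called the same way in both subsets, 1 (Prpf18, named after its values were seen) lies within 10 Mb of Il2ra, where 59 genes were tested: the odds ratio was 0.302 (95% interval 0.00751 to 1.76; Fisher's exact p = 0.376, two-sided), too wide to exclude an excess there, though the other calls with known coordinates lie elsewhere. Nnt, whose deletion marks the C57BL/6J strain, was higher in all 3 KO than in all 3 WT libraries of each subset, by 1.55-fold in the subset with the smaller fold, less than the 2-fold set for a strain difference. Background strain and the deletion cannot be told apart from these values, and the labels used here name no strain.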
